A study of Homo sapiens with 6 samples.

How the data were processed

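The series holds 6 stranded polyadenylated RNA libraries from xenografts of MCF7 cells, 3 with ectopic wild-type MED1 and 3 with ectopic 6KR MED1. Per the labels' protocols, RNA was isolated with a QIAGEN RNeasy kit and libraries were made with a TruSeq stranded mRNA kit. Group and replicate number were taken from the labels. No label states that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

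The authors deposited one table of raw counts per human Ensembl gene, with whole numbers for 38606 genes and no normalization. Per the submitters' processing notes, STAR 2.5.2b, SAMtools 1.10 and DESeq2 were used, with the builds hg38 and mm10, whose roles are not given in the sources used here. The counting tool, annotation release, strand setting and handling of mouse reads are not given in the sources used here either. The table holds 0 mouse gene identifiers, so mouse stromal reads either were set aside before counting or were counted on human genes; the counts alone do not tell which. Without a stated strand setting, overlapping and antisense genes are uncertain.

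Symbols were found for 25643 identifiers in the name tables provided, and 34436 identifiers matched GENCODE release 29 on GRCh38, from which the coordinates were taken (1-based). In all, 8857 genes had a count of 0 in every library. Total counts were 48722352 to 71136246 per library, which makes counting error small against the spread between libraries for genes above a few CPM. Each library was counted as 1 sample. Counts of library pairs differed far beyond sampling noise (chi-square per gene of at least 113), which does not tell whether they came from separate animals. The share of counts in the 10 most abundant genes was 5.15 ± 0.50% in WT and 4.69 ± 0.49% in 6KR (mean ± SD, n = 3; exact permutation test, two-sided p = 0.6, smallest possible 0.1).

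Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust set, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error was taken as the absolute log2 fold change divided by the square root of F. CPM values in the text are scaled by TMM, except the summed cell type markers and values given as without TMM scaling, which are relative to total counts alone. Fold changes are 6KR minus WT on the log2 scale. The 27 gene lists, with 562 members of which 560 matched a symbol, were tested with camera in limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, where at least 3 members were tested, with adjustment over the 26 lists so tested. Medians of lists, and their counts of higher and lower members, are of differences between group means of voom log2 CPM. Estimated correlations and fry, for one direction and for mixed directions, were also run.

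The lists were heat shock chaperones, integrated stress response, ER chaperones, NRF2 targets, hypoxia, p53 targets, estrogen response, luminal and basal identity, E2F targets, G2/M, interferon response, MHC class I, NF-kB, immediate early genes, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, Mediator, mitochondrially encoded genes and markers of fibroblasts, endothelium, leukocytes, adipocytes, smooth muscle and skeletal muscle.

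The lists, the tests, the other settings and the rule for named genes were set before the data were examined. The rule named MED1 and ESR1, any Mediator gene that passed, and up to 12 genes per direction that passed, with a mean of at least 2 CPM and groups that do not overlap. As fewer than 5 passed in a direction, the 5 with the smallest p in each direction were named as values. From each list up to 4 members that passed were named or, as none did, the member with the smallest p. TFF1, MYB, SIAH2, FN1, CA9 and ICAM1 were named after their values were seen.

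The other settings were scaling by the median ratio of DESeq2 (RLE), the Wald test of DESeq2 1.42.0, no filter on low counts, the replicate number as a block and leaving out each library in turn. Leaving out each library in the DESeq2 test, and in the list test with an estimated correlation, was added after 6KR replicate 1 was seen to stand apart. The edgeR, DESeq2 and camera tests were run on simulated counts with the means, dispersions and library sizes of the real data. Changes were placed only in genes of at least 2 CPM. Each gene had the same dispersion in every library, so a library that stands apart was not simulated. Of 150 genes changed 2-fold in 3 datasets edgeR recovered 22 and DESeq2 39, and of 150 changed 4-fold 106 and 132. Among the unchanged genes of these datasets edgeR called 40 and DESeq2 228. Of 4 lists shifted by 1 log2 unit all 4 were called, and of 26 unchanged lists 0. Genes in these simulated lists varied independently, whereas the estimated correlation of the real lists reached 0.87 (interferon response). The simulation therefore does not show how often the preset correlation calls unchanged lists whose members move together. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.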

Results

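RNA sequencing measured polyadenylated transcripts in xenografts of MCF7, an estrogen receptor positive human breast cancer cell line. MED1 is a subunit of Mediator, the complex that links transcription factors such as the estrogen receptor to RNA polymerase II. In the study's engineered MCF7 cells, endogenous MED1 was depleted and ectopic MED1 was expressed in its place. The series compared 3 libraries with ectopic wild-type MED1 (WT) and 3 with ectopic 6KR MED1 (6KR), a mutant named for 6 lysine-to-arginine changes. Arginine cannot be acetylated as lysine can, and the series' title names MED1 acetylation as the subject. Total counts were 48722352, 62625018 and 71136246 in the WT libraries and 70563759, 66157048 and 56920003 in the 6KR libraries. The group totals differed by less than their spread (exact permutation test, two-sided p = 0.7, smallest possible 0.1).

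MED1 transcripts varied more within the groups than between them. MED1 (ENSG00000125686; chromosome 17, 39404285 to 39451286, GRCh38) stood at 665, 236 and 1552 CPM (counts relative to library size, scaled by TMM) in the WT libraries. It stood at 1861, 621 and 1187 CPM in the 6KR libraries. The log2 difference, 6KR minus WT, was 0.58 (SE 0.68, n = 3 per group; edgeR adjusted p = 0.926), and leaving out single libraries moved it between 0.14 and 1.44. Reads of the ectopic and any remaining endogenous MED1 are counted together, so these values check neither the depletion nor the mutation. Of the 32 Mediator subunits and kinase module members measured, 0 passed the gene test. The lowest p among them belonged to MED14, a scaffold subunit, at 83.2 ± 8.2 CPM in WT and 123 ± 11 in 6KR (mean ± SD, n = 3). ESR1, which encodes estrogen receptor alpha (chromosome 6, 151656691 to 152129619), was at 1527 ± 301 CPM in WT and 1213 ± 410 in 6KR. Its log2 difference of -0.33 (SE 0.29; edgeR adjusted p = 0.903) lay within the replicate spread.

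The comparison of 6KR with WT tumors asked which genes depend on lysines of MED1 that can be acetylated. The gene nearest to a call was CREB3L1, an endoplasmic reticulum bound transcription factor of the CREB family (ENSG00000157613; chromosome 11, 46277661 to 46321422). It was at 11.6 ± 2.9 CPM in WT and 96.0 ± 17.1 in 6KR, a log2 difference of 3.05 (SE 0.26; edgeR adjusted p = 0.0591). Each of the 3 6KR libraries lay above all WT libraries, at 84.6, 116 and 87.7 CPM. CXCL12, a chemokine gene induced by estrogen (chromosome 10, 44370165 to 44386493), lay at 13.7 ± 2.6 CPM in WT and 2.13 ± 0.42 in 6KR, a log2 difference of -2.68 (SE 0.31). GREB1, an estrogen receptor target and cofactor (chromosome 2, 11482341 to 11642788), was at 331 ± 98 CPM in WT and 98.4 ± 35.5 in 6KR, a log2 difference of -1.75 (SE 0.34). For CXCL12 and GREB1 the edgeR adjusted p over all genes was 0.275 and 0.866.

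The other genes with the smallest p had non-overlapping groups too. On the higher side, PTPRN2, a receptor phosphatase of secretory granules (chromosome 7, 157539056 to 158587788), was at 3.21 ± 0.59 CPM in WT and 15.1 ± 3.1 in 6KR. CALML5, a calmodulin-like protein (chromosome 10, 5498697 to 5499555), stood at 4.67 ± 1.67 and 19.8 ± 4.6 CPM. PPFIA2, a liprin scaffold gene (chromosome 12, 81257975 to 81759553), stood at 1.03 ± 0.36 and 12.1 ± 9.1 CPM, with 22.6 CPM in 6KR replicate 1. PAGE2, a member of a cancer-testis antigen family (chromosome X, 55089008 to 55092842), had 0, 4 and 0 counts in the WT libraries and 4829, 3733 and 660 in the 6KR libraries. The ratio of its depth-scaled group counts was 2170, with a 95% exact interval of 847 to 7967 that covers counting error only. PAGE2 shares near-identical sequence with PAGE2B, so how reads were divided between them is uncertain.

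On the lower side stood COL12A1, a fibril-associated collagen (chromosome 6, 75084326 to 75206051), at 44.4 ± 12.5 CPM in WT and 8.79 ± 3.56 in 6KR. NPY1R, a neuropeptide Y receptor induced by estrogen in breast cells (chromosome 4, 163323961 to 163344832), was at 17.7 ± 3.0 and 4.48 ± 1.68 CPM. TFPI2, a secreted serine protease inhibitor (chromosome 7, 93885396 to 93890991), was at 5.98 ± 1.12 and 1.21 ± 0.41 CPM. None of the 10 genes named by smallest p passed in edgeR, and all 10 passed in DESeq2, with adjusted p from 3.26e-19 for CREB3L1 to 0.00243 for GREB1. The genes were picked by p in these same libraries, so neither the DESeq2 calls nor the non-overlapping groups are separate support. Leaving out single libraries ended 1 of these DESeq2 calls, that of GREB1 without WT replicate 1, at a log2 difference of -1.50 (SE 0.42; adjusted p = 0.0781).

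**Figure D1:**
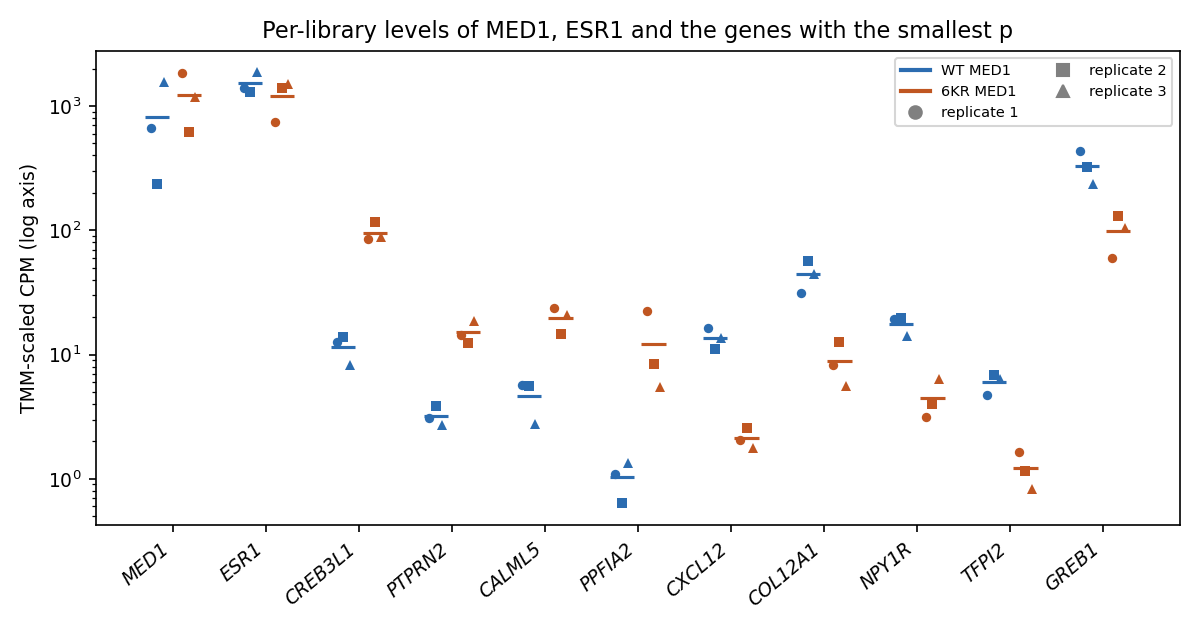
TMM-scaled CPM on a log axis for MED1, ESR1 and 9 of the 10 genes with the smallest p (PAGE2, with zeros, is left out). Blue marks are WT and orange marks 6KR libraries, shapes give the replicate number and bars the group means; MED1 overlaps between groups, while CREB3L1 lies at 8.26 to 13.8 CPM in WT and 84.6 to 116 CPM in 6KR.

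Over all genes, 0 of 19642 tested passed edgeR's quasi-likelihood test at an adjusted p of 0.05, whereas DESeq2 called 106 genes, 87 higher and 19 lower in 6KR. At an unadjusted p under 0.05 edgeR had 1063 genes, 723 higher and 340 lower, where 982.1 would fall by chance. The groups did not overlap in 2100 genes (10.7%), and chance gives 10%. In simulated data without any change, DESeq2 called 58, 31 and 40 genes and edgeR 0, 2 and 0 in 3 datasets of the same size. With simulated changes, placed in genes of at least 2 CPM, edgeR recovered 14.7% of 2-fold, 70.7% of 4-fold and 92.7% of 8-fold changes. In 72 of the 87 higher genes the highest library was 6KR replicate 1. Without that library DESeq2 called 114 genes, 62 higher and 52 lower, of which 45 were among the 106; edgeR then called 1, CREB3L1 (adjusted p = 0.0345). Without 6KR replicate 2 or 3 DESeq2 called 214 and 356 genes.

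The 6KR replicate 1 library stood apart from the rest. Its correlation with the other 5 libraries on log2 CPM was 0.918 to 0.934, against 0.961 to 0.975 among those 5. The first principal component, with 43.9% of the variance, separated it. Genes of hypoxia and glycolysis lay high in it and interferon-induced genes lay low, as described beside each group.

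Estrogen-responsive genes were lower in 6KR as a group. Of the 30 genes on this list, 21 had a lower mean log2 level in 6KR and 9 a higher one, and the median log2 difference was -0.33. The list passed limma's camera with the preset correlation (adjusted p = 0.00069 over 26 lists), and not with an estimated correlation (adjusted p = 0.485). Over all genes 0 members passed in edgeR and 2, CXCL12 and GREB1, in DESeq2 (GREB1 not without WT replicate 1, adjusted p = 0.0781); adjusted over the list alone, the same 2 passed in edgeR. MYB, a transcription factor gene, was at 96.7 ± 11.2 CPM in WT and 46.2 ± 21.7 in 6KR, and SIAH2, a ubiquitin ligase gene, at 151 ± 39 and 92.7 ± 11.1 CPM. The classical target TFF1 went the other way, at 3600 ± 1729 CPM in WT and 7391 ± 4680 in 6KR, within its spread. Without 6KR replicate 1 the list's median was -0.36 (adjusted p = 2.69e-07; 0.411 was the adjusted p with an estimated correlation). Without 6KR replicate 3 it was -0.19 (adjusted p = 0.00908; 0.566 was the adjusted p with an estimated correlation). Without WT replicate 1 the list's median was -0.27, with an adjusted p of 0.0372 (0.776 with an estimated correlation). The libraries' list means overlapped between the groups, with WT replicate 3 at -0.068 and 6KR replicate 1 at -0.005 log2 units from the mean of all 6. The highest list mean was that of WT replicate 1, at 0.533.

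Luminal and basal identity genes gave no gene that passed in edgeR. Of the 20 luminal epithelial genes, 10 were higher and 10 lower, with a median of -0.03 (camera adjusted p = 0.908; the test and the mean of 0.09 pointed up); the lowest p belonged to CLDN4, a tight junction claudin, at 205 ± 26 and 300.2 ± 49.9 CPM. Of the 16 basal and mesenchymal genes tested, 11 were higher in 6KR, with a median of 0.59 (adjusted p = 0.0359; adjusted p = 0.764 with an estimated correlation). EGFR, the epidermal growth factor receptor, was at 1.67 ± 0.40 CPM in WT and 5.0 ± 1.9 in 6KR and passed in DESeq2 (log2 difference 1.60, SE 0.40; adjusted p = 0.0241). Its call ended without WT replicate 1, WT replicate 3 or 6KR replicate 1, at log2 differences of 1.52, 1.47 and 1.23 (adjusted p = 0.173, 0.106 and 0.114). FN1, which encodes fibronectin, averaged 199 ± 293 CPM in 6KR against 18.8 ± 2.7 in WT. With an SD above the mean, its level was very uneven across the 6KR libraries. The basal list lost its call without WT replicate 1, WT replicate 3 or 6KR replicate 1, with medians of 0.35, 0.75 and 0.41 (adjusted p = 0.0765, 0.098 and 0.11). Its median was 0.97 without WT replicate 2 and 0.90 without 6KR replicate 3 (adjusted p = 0.0202 and 0.0266; 0.705 and 0.566 were the adjusted p with an estimated correlation).

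Hypoxia and glycolysis genes were higher in 6KR with replicate 1 included and not without it. Of 25 hypoxia-induced genes, 21 were higher, with a median of 0.40 (adjusted p = 0.00491; 0.819 was the adjusted p with an estimated correlation). All 18 glycolysis genes were higher, with a median of 0.41 (adjusted p = 0.000447; 0.764 was the adjusted p with an estimated correlation). ENO1, the glycolytic enolase, was at 784 ± 77 CPM in WT and 1196 ± 196 in 6KR. CA9, a hypoxia-induced carbonic anhydrase, averaged 24.5 ± 42.0 CPM in 6KR. The medians of 6KR replicate 1 lay 1.47 log2 units above the other 5 libraries for hypoxia and 1.24 for glycolysis. Without it the medians were -0.15 and -0.06 (adjusted p = 0.11 and 0.795). Without 6KR replicate 2 they were 0.62 and 0.66, and the hypoxia median was 0.616 without 6KR replicate 3. Without WT replicate 3 the hypoxia list, with a median of 0.33, was at an adjusted p of 0.0531.

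Interferon-induced genes turned with the same library. With all libraries 17 of 24 had a lower mean log2 level in 6KR, with a median of -0.16 (adjusted p = 0.638), although edgeR's fold changes, which weigh high libraries more, were positive for 20. In 6KR replicate 1 the list's median lay 2.68 log2 units below the other libraries (a deviation of -2.68), and in 6KR replicates 2 and 3 it lay 1.48 and 0.80 above. Without 6KR replicate 1 all 24 were higher, with a median of 0.68 (adjusted p = 2.86e-14; 0.411 was the adjusted p with an estimated correlation). Without 6KR replicate 2 the list passed in the other direction, with a median of -0.82 (adjusted p = 0.000412; 0.744 was the adjusted p with an estimated correlation). The lowest p belonged to IRF7, an interferon regulatory factor, at 44.6 ± 10.001 and 59.7 ± 20.3 CPM. For MHC class I antigen presentation, 10 of 15 genes were higher, with a median of 0.11 (adjusted p = 0.487); HLA-F stood at 17.1 ± 1.6 and 26.03 ± 13.17 CPM. That list passed without 6KR replicate 1, with a median of 0.26 (adjusted p = 0.00132; 0.51 was the adjusted p with an estimated correlation).

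**Figure D2:**
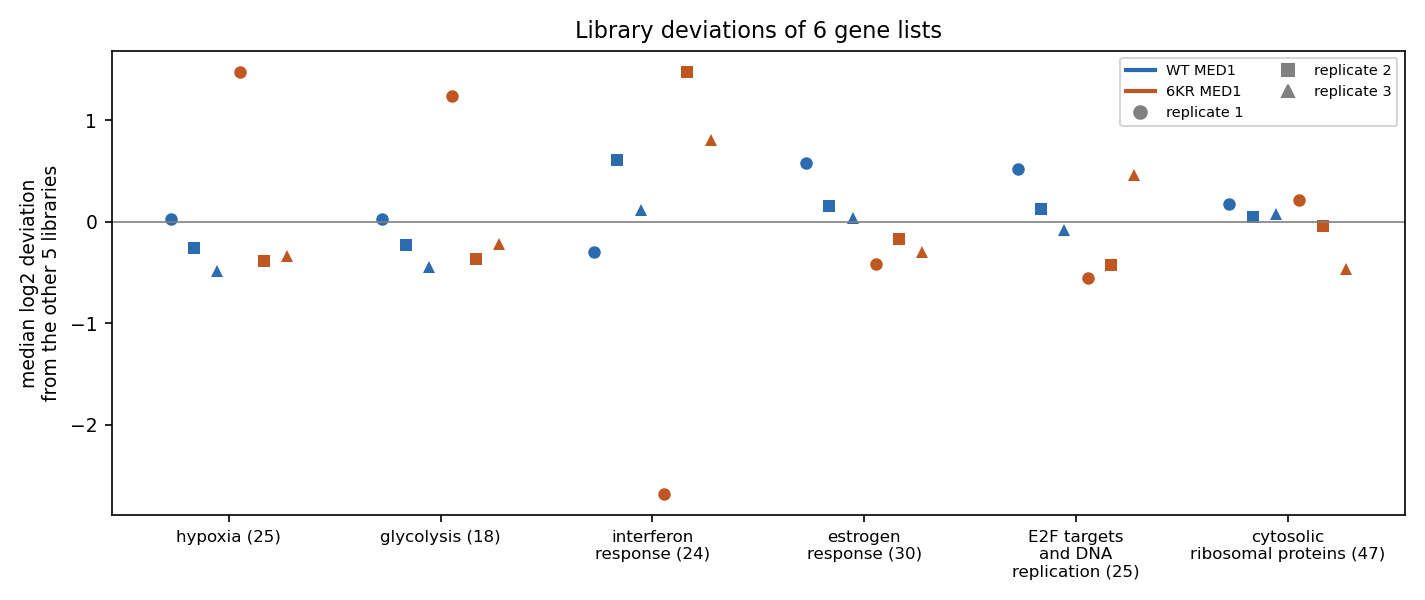
Median log2 deviation of each library from the mean of the other 5 for 6 gene lists, with the number of genes tested in parentheses. Blue marks are WT and orange marks 6KR libraries, and shapes give the replicate number; 6KR replicate 1 lies at 1.47 for hypoxia, 1.24 for glycolysis and -2.68 for interferon response, while the estrogen response medians lie higher in all WT than in all 6KR libraries and the means of that list overlap.

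Genes of NF-kB and inflammatory signalling were higher in 6KR, in 11 of 14 tested, with a median of 0.46 (adjusted p = 0.00305; 0.485 was the adjusted p with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, was at 2.80 ± 0.85 CPM in WT and 7.41 ± 2.41 in 6KR, and ICAM1, an adhesion molecule gene, at 2.71 ± 0.80 and 4.85 ± 0.94 CPM. Without 6KR replicate 2 the list's median was 0.31 (adjusted p = 0.15). The 4 myeloid and leukocyte markers tested, of 14 listed, lay higher too, with a median of 1.45 (adjusted p = 0.0181, and 0.764 with an estimated correlation). PTPRC, also on that list, was at 0 to 0.082 CPM across the libraries without TMM scaling, and at 0 in 6KR replicate 1. Immediate early genes did not pass as a list, with 12 of 21 lower and a median of -0.08 (adjusted p = 0.908). EGR1, a serum-induced transcription factor, was at 41.1 ± 13.6 CPM in WT and 83.7 ± 14.96 in 6KR, all 3 6KR libraries above the WT libraries.

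Cell cycle lists had lower medians in 6KR with all libraries, although the libraries overlapped. For replication and mitosis, 6KR replicate 3 lay 0.46 and 0.36 log2 units above the other libraries, against 0.52 and 0.27 for WT replicate 1, 0.13 in both for WT replicate 2 and -0.08 and -0.10 for WT replicate 3. Of 25 E2F targets and DNA replication genes, 22 were lower, with a median of -0.30 (adjusted p = 0.00052; 0.764 was the adjusted p with an estimated correlation). PCNA, the replication clamp, was at 141 ± 35 CPM in WT and 95.8 ± 29.7 in 6KR. For G2/M and mitosis, 20 of 25 were lower, with a median of -0.15 (adjusted p = 0.0172; 0.819 was the adjusted p with an estimated correlation), and CDC20, an activator of the anaphase-promoting complex, stood at 115 ± 2 and 91.03 ± 12.02 CPM. The replication list lost its call without WT replicate 1, 6KR replicate 1 or 6KR replicate 2 (medians -0.15, -0.16 and -0.18; adjusted p = 0.0762, 0.0586 and 0.0712), and its median was -0.51 without 6KR replicate 3. The mitosis list lost it without WT replicate 1 or 2 or 6KR replicate 1 or 2 (medians -0.08, -0.15, 0.0015 and -0.16; adjusted p = 0.254, 0.0574, 0.978 and 0.0696). Its median was -0.27 without WT replicate 3 and -0.32 without 6KR replicate 3.

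Integrated stress response genes and p53 targets were lower in 6KR. In the integrated stress response, 16 of 19 genes were lower, with a median of -0.27 (adjusted p = 0.00145; 0.485 was the adjusted p with an estimated correlation), and CEBPG, a C/EBP family transcription factor, stood at 85.6 ± 15.4 CPM in WT and 56.2 ± 8.9 in 6KR. This list passed with the preset correlation in each of the 6 fits that left out 1 library, and in 0 of them with an estimated correlation (the lowest adjusted p was 0.325). Of 20 p53 targets, 13 were lower, with a median of -0.17 (adjusted p = 0.0172; 0.485 was the adjusted p with an estimated correlation). BAX, a promoter of apoptosis, stood at 108 ± 4 and 80.2 ± 10.1 CPM. The p53 list lost its call without WT replicate 2, 6KR replicate 2 or 6KR replicate 3 (medians -0.20, -0.15 and -0.23; adjusted p = 0.0819, 0.0696 and 0.0856). Heat shock chaperones, ER chaperones and NRF2 targets did not pass, with medians of -0.09, 0.19 and -0.19 (adjusted p = 0.188 for each); heat shock chaperones passed downward without 6KR replicate 3, with a median of -0.19 (adjusted p = 0.0362; 0.623 was the adjusted p with an estimated correlation). The NRF2 median ran from -0.23 without WT replicate 3 to -0.05 without WT replicate 1 and -0.01 without 6KR replicate 2. Within these lists the lowest p belonged to HSPB1, SEC61B and AKR1C1. HSPB1, a small heat shock protein gene, stood at 2202 ± 291 and 1492 ± 212 CPM. The ER chaperone list passed without WT replicate 1, 6KR replicate 2 or 6KR replicate 3 (medians 0.25, 0.36 and 0.29; adjusted p = 0.0372, 0.0153 and 0.0362). With an estimated correlation the adjusted p in those fits was 0.917, 0.744 and 0.765. Its median in 6KR replicate 1 lay 0.77 log2 units above the other libraries.

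Cytosolic ribosomal protein genes were lower in 39 of 47, with a median of -0.15 (adjusted p = 0.000209; 0.764 was the adjusted p with an estimated correlation). RPS6 was at 1348 ± 492 CPM in WT and 783 ± 96 in 6KR. Without 6KR replicate 3 the ribosomal median was -0.01 (adjusted p = 0.49), and without 6KR replicate 1 it was -0.26. The Mediator list had a median of -0.12 (adjusted p = 0.188), and passed without 6KR replicate 3 with a median of -0.15 (adjusted p = 0.0362; 0.566 was the adjusted p with an estimated correlation); without WT replicate 1 its median was -0.06 (adjusted p = 0.525). Oxidative phosphorylation and cholesterol synthesis did not pass, with medians of 0.03 and -0.07 (adjusted p = 0.661 for each). NDUFS1, a complex I subunit, stood at 89.3 ± 1.4 and 118 ± 20 CPM, and LSS, lanosterol synthase, at 161 ± 20 and 295 ± 96 CPM. Cholesterol genes passed downward without 6KR replicate 1, with a median of -0.33 (adjusted p = 6.3e-05; 0.411 was the adjusted p with an estimated correlation).

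Markers of other cell types were tested as 6 lists. The 4 myeloid and leukocyte genes tested, of 14 on the list, were all higher in 6KR, with a median of 1.45 (adjusted p = 0.0181; 0.764 was the adjusted p with an estimated correlation). PTPRC, also on the list, was at 0 to 0.082 CPM across the libraries without TMM scaling. CD74, the MHC class II invariant chain, was at 2.95 ± 1.15 CPM in WT and 11.8 ± 11.1 in 6KR, with 24.5 CPM in replicate 1. The list's median lay 2.83 log2 units above the other libraries in 6KR replicate 1, and the median difference without that library was 0.89 (adjusted p = 0.012; 0.411 was the adjusted p with an estimated correlation). Without WT replicate 1 this list's median was 1.22 (adjusted p = 0.0652). Of 18 fibroblast genes 8 were tested, with a median of 0.48 (adjusted p = 0.0819), and the list passed without 6KR replicate 1 or without WT replicate 3 (medians 0.36 and 0.63; adjusted p = 0.0331 and 0.00289; 0.51 and 0.325 were the adjusted p with an estimated correlation). COL6A1, a collagen VI chain, was at 248 CPM in 6KR replicate 1 and at 17.1 to 46.9 CPM in the other libraries. The endothelial, adipocyte, smooth muscle and skeletal muscle lists did not pass, with medians of 0.17, -0.13, -0.14 and 0.41 (adjusted p = 0.993, 0.438, 0.908 and 0.438). The skeletal muscle median was 0.24 without WT replicate 3 and 0.80 without 6KR replicate 3, and the fibroblast median 0.76 without 6KR replicate 3. The endothelial, adipocyte and smooth muscle medians ran from 0.013 to 0.407, -0.66 to 0.16 and -0.27 to 0.18 leaving out single libraries. The median and the test pointed up for the endothelial list while its mean was -0.22, and the smooth muscle test pointed up against its median. ENG, the endothelial receptor endoglin, stood at 26.9 ± 12.3 CPM in WT and 11.5 ± 2.1 in 6KR. PLIN4, MYLK and TTN had the lowest p in the remaining lists. The 13 mitochondrially encoded genes were listed at 0 in every library, so their share says nothing about RNA quality here.

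**Figure D3:**
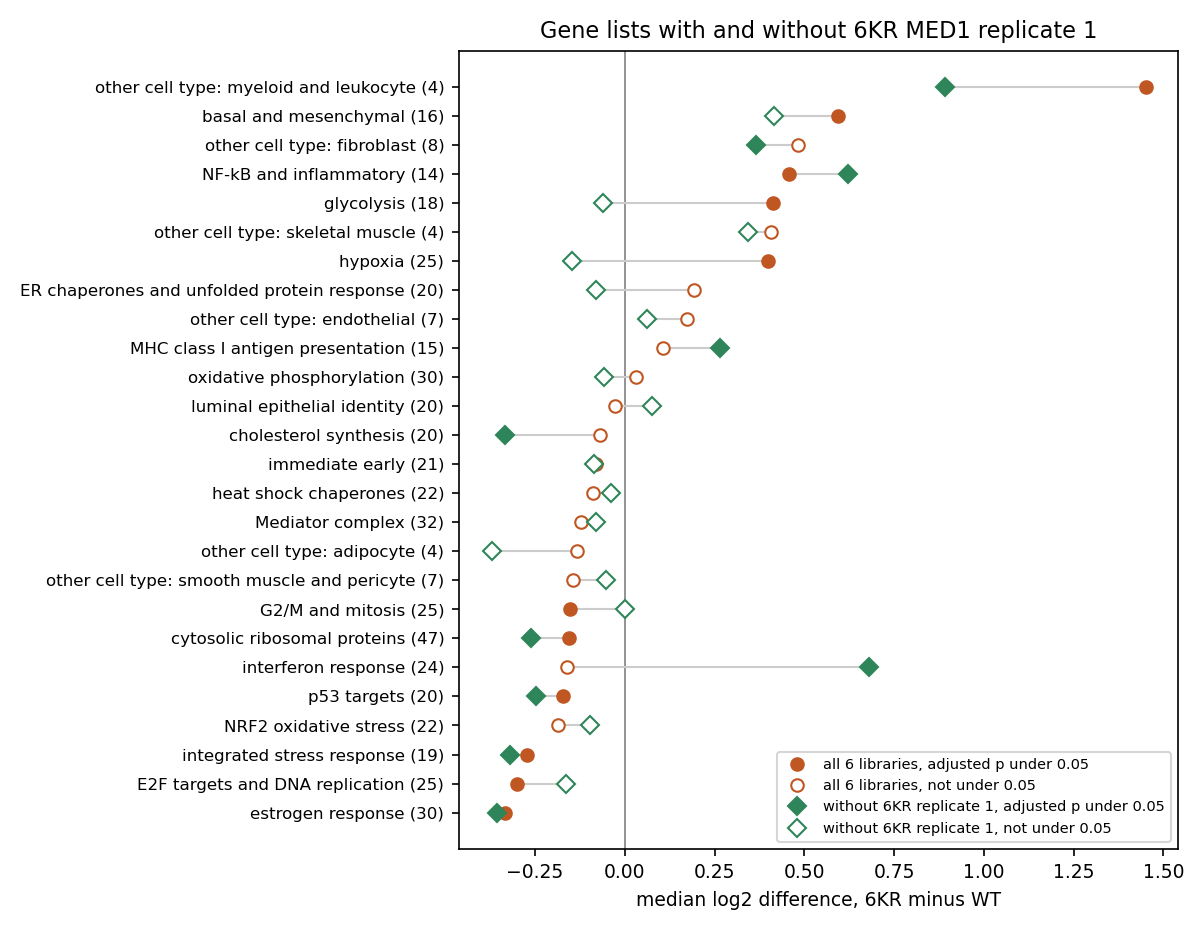
Median log2 difference (6KR minus WT) of 26 gene lists, with the number of genes tested with all 6 libraries in parentheses. Orange circles use all 6 libraries and green diamonds leave out 6KR replicate 1; filled marks have an adjusted p under 0.05 in camera with the preset correlation, and the medians of hypoxia, glycolysis, interferon response, G2/M, ER chaperones, luminal identity and oxidative phosphorylation change sign between the fits.

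In all, 11 of the 26 lists passed with the preset correlation, 5 higher and 6 lower in 6KR, and 0 with an estimated correlation or in fry. Without 6KR replicate 1, 10 lists passed, 6 of them among the 11 and in the same direction, and 0 passed with an estimated correlation (the lowest adjusted p was 0.411).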

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

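Leaving out each library in the DESeq2 test, and in the list test with an estimated correlation, was chosen after the data were seen; all other settings were planned. Scaling over mouse and human genes together was not run, since the table holds none. RLE scaling called 0 genes, as TMM did, and moved the median fold change by 0.013 log2 units. The gene count of 0 became 106 with DESeq2 (at least 2-fold: 106) and 1 without a low-count filter (at least 2-fold: 1), and ranged from 0 to 1 over the fits leaving out a library (at least 2-fold: 0 to 1). The gene in each count of 1 was CREB3L1, at adjusted p = 0.00149 without the filter and 0.0345 without 6KR replicate 1. Over all alternatives its adjusted p ran from 7.63e-21 (DESeq2 without WT replicate 3) to 0.721, the latter in an edgeR fit. DESeq2 counts leaving out a library ran from 76 (without WT replicate 1) to 356 (without 6KR replicate 3), and the share of higher calls was 54.4% without 6KR replicate 1 against 82.1%. The MED1 difference stayed above 0 and past no threshold, at 0.14 to 1.44. Over the other named genes, 337 values under alternatives kept direction and side of the threshold, 13 passed it (11 with DESeq2, 2 for CREB3L1 as above) and 0 reversed.

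The list count of 11 became 0 with an estimated correlation, 0 with fry for one direction and 0 with fry for mixed directions, and ran from 8 to 12 leaving out a library (0 in each of these 6 fits with an estimated correlation). Of the list values under alternatives, 212 kept direction and side, 38 lost the threshold, 10 gained it and 26 reversed in the test's direction. The reversed ones were the endothelial list under RLE (0.19), the luminal list without a filter (-0.024) and, with the replicate block, the luminal (-0.023) and interferon (0.0019) lists. Leaving out a library reversed these lists at least once, with medians from lowest to highest of -0.188 to 0.031 for heat shock, -0.081 to 0.36 for ER chaperones, -0.15 to 0.62 for hypoxia, -0.126 to 0.076 for luminal, -0.32 to 0.0015 for G2/M, -0.82 to 0.68 for interferon, -0.043 to 0.264 for MHC class I, -0.236 to 0.017 for immediate early, -0.33 to 0.12 for cholesterol, -0.061 to 0.659 for glycolysis, -0.058 to 0.117 for oxidative phosphorylation, 0.013 to 0.407 for endothelial, -0.66 to 0.16 for adipocyte and -0.27 to 0.18 for smooth muscle. The cause was not tested. With the replicate number as a block edgeR called 0 genes and camera 11 lists. Same-numbered libraries deviated together with correlations of 0.118, 0.072 and 0.057, and 2 of 3 correlated best with their own number. Correlations across numbers ran from -0.18 to 0.097. So few pairs cannot show whether a replicate number marks a shared factor.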

Other observations

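Tests of the estrogen list without 6KR replicate 1 and of ESR1 were chosen after the result was seen; the other tests were chosen before.

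Several genes set 6KR replicate 1 far apart; those named here, of at least 20 mean CPM, were chosen after their values were seen. ITIH2, an inter-alpha-trypsin inhibitor heavy chain, was at 593 CPM there and at 0.71 ± 0.53 in the other 5 libraries (mean ± SD). MUC5AC and MUC5B, gel-forming mucins, were at 329 and 3091 CPM against 0.93 ± 1.00 and 20.5 ± 22.4. PCSK9, which lowers LDL receptor levels, was at 332 CPM against 0.76 ± 0.55. On the low side, GDNF, a neurotrophic factor, was at 0.17 CPM against 28.4 ± 11.8, and the interferon-induced XAF1 and IFIT1 were at 1.61 and 2.34 CPM against 131 ± 73 and 108 ± 51. At least 4-fold deviations from the other 5 libraries were found for 499 higher and 217 lower genes of 13685, where the other libraries had 24 to 55 higher and 26 to 165 lower.

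Mixed-in stromal cells, sequence bias and copy number were weighed as technical explanations for this library. Reads from mouse or other stromal cells dilute tumor transcripts by at most their share, so the 217 genes at least 4-fold lower would need a share near 75%. The 44 markers of fibroblasts, endothelium and leukocytes summed to 842 CPM there without TMM scaling, the highest of the 6 (228 to 558 in the others), with COL6A1 at 248 CPM against 17.1 to 46.9. COL1A1 was at 61.9 against 26.3 to 57.2 (58.5 against 25.9 to 58.9 without TMM) and COL3A1 at 51.2 against 11.5 to 113. Other markers were near or at 0 there without TMM scaling: COL1A2 at 0.028 CPM, PECAM1 at 0.14, PTPRC and CDH5 at 0. Each of these was at most 0.25 CPM in every other library too. For human cells of these kinds, a marker sum far below such a share argues against them as the source of the lower genes. A small share stays open. For mouse cells the sum cannot decide. How mouse reads were handled is not known, nor how many would be counted on the human markers. Transcript length and GC content hardly followed the deviation across genes (Spearman rho 0.0023 and 0.14; genes are not independent replicates), which argues against both as the source. Windows of 50 neighbouring genes explained 7.29% of the variance of the deviation, against 2.03% with gene order permuted, so chromosome segments do not account for it. Other sources were not weighed, among them how the tumor piece was taken or grown. The stromal marker sum does not measure a share of cells outside those marker groups. No biological explanation was tested, since the design names none for a single library.

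For the lower estrogen-responsive genes in 6KR, 6KR replicate 1 alone is argued against by the median of -0.36 without it (adjusted p = 2.69e-07 with the preset correlation; 0.411 was the adjusted p with an estimated correlation). Without WT replicate 1 the median was weaker, at -0.27 (adjusted p = 0.0372 with the preset correlation, 0.776 with an estimated correlation). Whether the MED1 transcript level plays a part was not decided, and that level did not differ between the groups beyond its spread (log2 difference 0.58, SE 0.68). The list's mean level went with MED1 log2 CPM over the 6 libraries at r = -0.26 (exact permutation p = 0.614) and Spearman rho = -0.09 (exact permutation p = 0.919), the only relation computed. Leaving out the 2 libraries farthest in MED1 gave r = -0.28, and leaving out single libraries gave -0.42 to -0.19. All these values were weak. So few libraries, pooled over both groups, cannot tell a weak relation from none. A lower ESR1 level could also take part, since its difference of -0.33 has a 95% interval of -1.14 to 0.48. That interval was built on 4 degrees of freedom, fewer than the moderated edgeR test has, so it is wider than that test implies. The mutation itself, which the groups are built on, stays open beside these.

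The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. By edgeR the real split called 0 genes, the highest other 0, and all 10 splits gave as many. With DESeq2 the real split called 106 and the highest other 175, and 3 of the 10 gave as many as the real one. For gene lists the real split passed 11 and the highest other 15, and 5 of the 10 gave as many.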
